A study of Mus musculus with 2 samples.

How the data were processed

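The samples were 2 single-cell RNA-seq libraries of CD45-positive cells from E0771 tumours, 1 for each treatment (AAV-Vector and AAV-p-MAEGI), each from a pool of 3 mice. Per the labels' protocols the libraries were made with the 10x Genomics Chromium 3' kit, in which each molecule carries a UMI. Per the submitters' processing notes Cell Ranger 1.3 and the mouse genome build mm10 were used. The deposited count table holds UMI counts per Ensembl gene and barcode over both libraries, whole numbers that are not normalised. Whether the authors thinned reads to equal depth when the libraries were joined, and how barcodes were chosen, is not given in the sources used here. The authors' deposited embedding table holds t-SNE coordinates as a score with no fixed scale and without barcodes, and was used only to check which barcodes it covers. For that check the number of its rows was searched for among many minimums of UMIs and genes, some with a limit on mitochondrial UMIs or a need for Ptprc.

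Barcodes end in 1 of 2 suffixes. Nothing in the labels or the files used here says which suffix belongs to which treatment, and sample order was not used in its place. As fixed before the data were examined, the table was then treated as 1 pooled sample and no treatment comparison was made. Values of the suffixes, called barcode set 1 and barcode set 2, are given apart as unassigned samples. With 1 library per treatment there is no test, no p-value and no count of changed genes.

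Gene symbols came from a reference table of Ensembl identifiers, which matched 27645 of 27998 genes. Of 365 places in the 16 fixed gene lists, 362 had a gene under the listed symbol. Over the lists and cell type markers, no gene was found under the symbols Cd244, Ighd, Ighm, Igj, Iglc2, Iglv1, Lilrb4a, Mx2, Tcrg-C1, Tcrg-C2, Trac, Trbc1, Trbc2 and Trdc, which leaves the T cell and B cell markers without their receptor constant genes. Gene positions came from the GENCODE annotation of GRCm38, the build also called mm10.

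Barcodes with at least 200 genes and under 10% mitochondrial UMIs were kept, which left 16686 of 20000, 6734 in barcode set 1 and 9952 in barcode set 2. Counts were scaled to 10000 per barcode and log-transformed. The 2000 genes with the highest dispersion, standardised within 20 bins of mean, were scaled and reduced to 30 principal components (scikit-learn 1.9.0). A shared-neighbour graph of 15 neighbours (igraph 0.11.9) was clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, Python 3.11.15), which gave 21 clusters. Doublets were kept. Scrublet, run in scanpy 1.11.5 on each barcode set, called 0 of 16686 barcodes, so the caller did not work here and the removal of its calls, an alternative fixed beforehand, could not be run. In the mixed cluster the median Scrublet score was 0.278, against 0.0568 over all kept barcodes.

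The marker lists were fixed before the data were examined, but the rule that turns them into names was not, and it was changed after the clusters had been seen. A cluster was named when at least 3 markers of a class were raised 2-fold and their mean log2 fold was at least 1. The first rule compared a cluster with all other cells. It named cluster 8 NK-like and left clusters 10, 11 and 15 unnamed, and it was replaced by a comparison with the unweighted mean of the other clusters, under which cluster 11 was B-like. The threshold for a second lineage was then lowered to 0.5, which left cluster 11 B-like. A last rule sets a cluster apart as mixed when over 50% of its barcodes have UMIs of a Cd3 gene and of Cd79a or Cd79b. This rule keeps cluster 11 out of the B-like class. The rules named cluster 8 CD8 T-like and cluster 10 cycling B-like, but among their 10 leading genes both have more markers of another class than of their own, so the text leaves them unnamed and gives them by number. Cluster 11 held 1.83% of the barcodes, 0.772% in barcode set 1 and 2.54% in barcode set 2.

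Levels are CPM, the summed UMIs of a gene or list over all UMIs of the cluster, with exact Poisson intervals. Shares have exact Clopper-Pearson intervals, and both are at 95% (scipy 1.17.1). The rule fixed for naming genes ranked them by the ratio between treatments and could not be applied without a map of barcodes to treatments. The report therefore names the 7 genes fixed for CD8 T cells, members of the fixed lists, markers and leading genes of clusters. Which of these to name, apart from the 7, was chosen after their values were seen. For the barcode sets the fixed rule was applied to log2 of set 2 over set 1 with 10 CPM added, among genes with at least 50 UMIs and UMIs in at least 5% of the cells of one set. Of the genes it ranks, the text names a part, also chosen after the values were seen.

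A list's median ratio over members with at least 10 UMIs was placed among 10000 random lists matched on mean expression. Ratio and percentile were tested on simulated counts with 200 changed genes, 50 at each of 4 folds. For cluster 9, over 2267 genes, 96% of genes raised 2-fold and 90% of those lowered to 0.25 of their level came within 0.5 of the true log2 ratio. For the same cluster, with lists drawn from 5875 genes, 4% of unchanged lists fell outside the central 95%. The simulation drew each gene independently from the profile pooled over both sets, and its unchanged lists were random genes. It therefore does not cover lists whose genes rise and fall together, or differences between libraries.

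Alternatives fixed beforehand were other filters on barcodes, cluster resolutions of 0.5 and 2, marker genes per cell in place of clusters, each barcode set clustered alone, another denominator, other totals and scalings, equal weight for each barcode or class, thinning of each barcode to 1000 UMIs, another pseudocount and other gene filters. Those added after the data were seen were barcodes over 2000 UMIs, removal of barcodes with a Scrublet score over 0.25, clustering without the list genes, all cells without clusters 5 and 18, both earlier naming rules, clusters 8 and 10 without a name, and shares per set with the lowest UMI count of set 2 as the limit in both. The 3 lists whose ratios between barcode sets were taken through the alternatives were chosen after all 16 had been seen.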

Results

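The study profiled single CD45-positive cells sorted by flow cytometry from E0771 tumours, which grow from a mouse mammary carcinoma line, in C57BL/6J mice. CD45, encoded by Ptprc, is carried by most white blood cells. The treatments were labelled AAV-Vector and AAV-p-MAEGI, where AAV stands for adeno-associated virus, in a study of CRISPR activation of several endogenous genes and of immunity to tumours. Each treatment had 1 library from a pool of 3 mice, so the question the design poses, how the treatment changes the immune cells of the tumour, has no replicate. The deposited count table held 20000 barcodes and 27998 genes, with 87516431 unique molecular identifiers (UMIs). Its barcodes ended in 1 of 2 suffixes with 10000 barcodes each, 48190463 UMIs for suffix 1 and 39325968 for suffix 2. No label used here tied a suffix to a treatment, so both were analysed as 1 pooled sample and no difference between the treatments is given. The suffixes are called set 1 and set 2. A filter on genes and mitochondrial UMIs kept 16686 barcodes with a median of 1877 UMIs. Shares have exact Clopper-Pearson intervals and levels exact Poisson intervals, given in parentheses at 95%, which cover counting error only. Levels are in CPM, the UMIs of a gene or list scaled by all UMIs of the cluster. Of 95 pooled levels given, 20 were over 1.5 times from the level of 1 set alone, and the levels or UMIs of both sets stand beside those. The pooled level lies between the sets, so some of the others also differed over 1.5 times between sets. In cluster 4 type I interferon response genes were at 22019 CPM in set 1 and 12926 in set 2. In cluster 9 Havcr2 was at 55.4 and 30.8 and Lag3 at 107 and 64.6. In cluster 7 Ctla4 was at 176 and 104. Clusters were built from the same counts, so the genes that lead a cluster describe it and do not test it.

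To describe which cells the sort had collected, the barcodes were clustered and named by marker lists fixed before the data were examined. B-like cells, marked by the B cell receptor component Cd79a and by Fcmr, were the largest class over all kept barcodes, at 35.5% (95% interval 34.8 to 36.3%) of them, 23.3% in set 1 and 43.8% in set 2. CD4 T-like cells made up 16% (95% interval 15.4 to 16.5%) and CD8 T-like clusters 2 and 9 15.7% (95% interval 15.2 to 16.3%). Macrophage-like cells reached 8.22% (95% interval 7.80 to 8.64%), 13.5% in set 1 and 4.61% in set 2, and monocyte-like cells 5.44% (95% interval 5.10 to 5.80%), 9.98% in set 1 and 2.37% in set 2. Conventional, migratory and plasmacytoid dendritic-like cells together held 2.91% (95% interval 2.66 to 3.17%), 4.63% in set 1 and 1.74% in set 2. NK-like cells made up 1.10% (95% interval 0.944 to 1.27%) and plasma-like cells 0.336% (95% interval 0.254 to 0.436%). Neutrophil-like cells held 0.156% (95% interval 0.102 to 0.228%) of the kept barcodes, with 20 barcodes in set 1 and 6 in set 2. Their median was 664 UMIs and 282 genes, near the filter of 200 genes and below 840 UMIs, the lowest count in set 2. These minimums may limit their share and its split between sets, which was not tested. Fibroblast-like cells, which a CD45 sort should remove, reached 0.228% (95% interval 0.161 to 0.312%). A cluster in which 93.4% of the barcodes had UMIs of both a Cd3 gene and Cd79a or Cd79b was set apart as mixed and held 1.83% (95% interval 1.63 to 2.04%), 0.772% in set 1 and 2.54% in set 2. The lowest UMI count of a kept barcode was 256 in set 1 and 840 in set 2. With at least 840 UMIs in both sets, a limit chosen after the shares were seen, B-like barcodes made up 22% of set 1 and 43.8% of set 2, and macrophage-like barcodes 13.6% and 4.61%.

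Clusters 8 and 10 had more markers of another class than of their own among their 10 leading genes and are given by number, without a name. The naming rule by itself had counted cluster 8, 3.41% (95% interval 3.14 to 3.70%) of the barcodes and 1.75% in set 1 and 4.53% in set 2, as CD8 T-like, which put that class at 19.2%. It had called cluster 10, 2.65% (95% interval 2.41 to 2.90%) of the barcodes and 1.16% in set 1 and 3.66% in set 2, a cycling B-like cluster. The rule tried first placed cluster 8 with NK cells, which put the NK-like share at 4.51%. B-like cells with cluster 10 fell from 38.2% to 14.9% when only barcodes over 2000 UMIs were clustered, below the 28.9% then named CD8 T-like. B-like barcodes had a median of 1299 UMIs. Over all alternatives, which place cluster 8 differently, the shares were 14.9 to 41.0% for B-like cells and those of cluster 10 that went with them, 8.55 to 28.9% for CD8 T-like, 1.51 to 18.2% for CD4 T-like, 0.623 to 4.51% for NK-like, 5.17 to 22% for monocyte- and macrophage-like, and 2.30 to 4.83% for dendritic-like cells, and the lowest CD4 T-like, NK-like and macrophage-like shares came from calling cells by a few marker genes each.

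**Figure D1:**
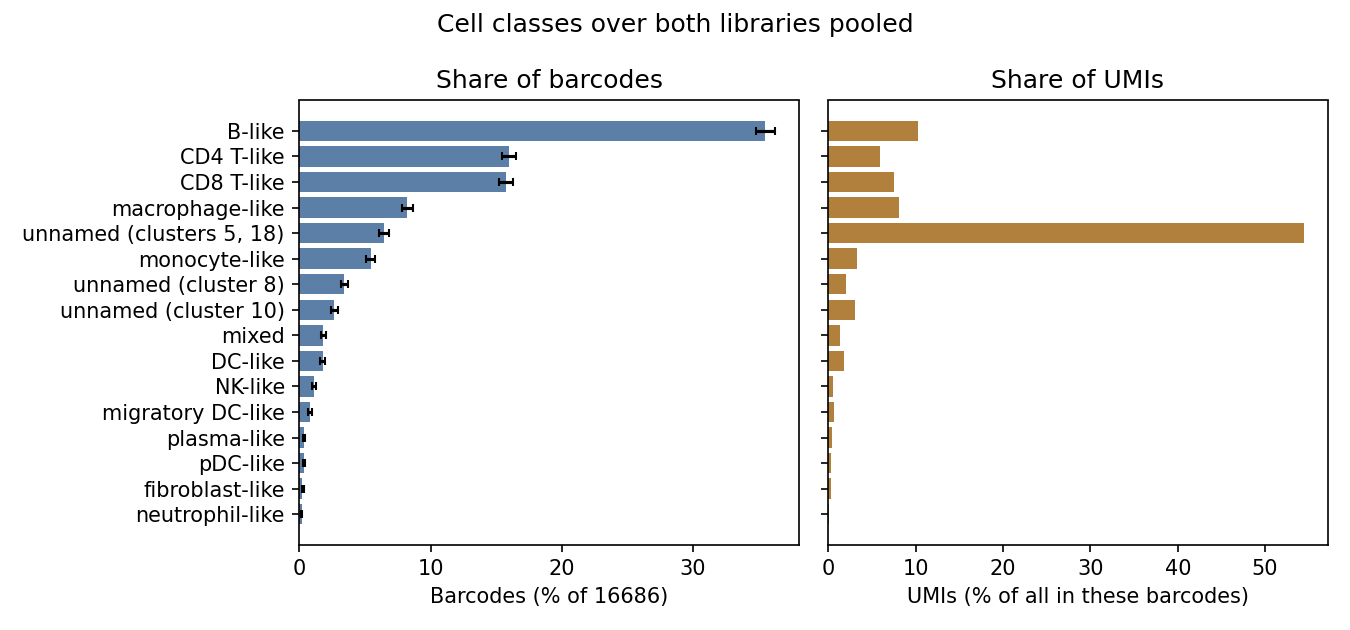
Shares in percent of the 16686 barcodes (left, bars with exact 95% binomial intervals) and of their UMIs (right) in each class, both libraries pooled, with clusters 5, 8, 10 and 18 unnamed. B-like cells held 35.5% of the barcodes and 10.2% of the UMIs, and clusters 5 and 18 6.46% of the barcodes and 54.4% of the UMIs.

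CD8 T-like clusters 2 and 9 differed in naive and effector genes. Cluster 2 (12.8% of barcodes, 95% interval 12.3 to 13.3%) had naive and memory T cell genes at a summed 3244 (3193 to 3294) CPM, with Dapl1, Txk, Klf2 and Cd27 the most abundant. Its cytotoxic effector genes summed to 1760.3 (1723 to 1798) CPM, of which Nkg7, a protein of cytotoxic granules, gave 49.8%. Cluster 9 (2.94% of barcodes, 95% interval 2.69 to 3.21%) had cytotoxic effectors at 24231 (23988 to 24476) CPM and naive and memory genes at 728 (686 to 771.4). Inhibitory receptor and exhaustion genes summed to 954 (907 to 1004) CPM in cluster 9 and 323 (308 to 339.7) in cluster 2.

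The 7 genes fixed beforehand for CD8 T cells were read in the same clusters. Gzmb, which encodes a granzyme that cytotoxic cells release into their targets, stood at 1343 (1287 to 1402) CPM in cluster 9 and 2.24 (1.12 to 4.0) in cluster 2. In B-like cells, which should lack it, Gzmb was at 3.05 (2.01 to 4.44) CPM. Ifng, the gene of interferon gamma, was at 522 (487 to 559) CPM in cluster 9 and 2.03 (0.975 to 3.74) in cluster 2, the latter from 2 UMIs in set 1 and 8 in set 2. Among checkpoint receptor genes, Pdcd1 was at 67.4 (55.2 to 81.6) CPM in cluster 9, Lag3 at 80.8 (67.4 to 96.1) and Havcr2 at 40.1 (30.8 to 51.3). Tcf7, a transcription factor of naive and memory T cells, was at 8.91 (4.87 to 14.9) CPM in cluster 9 and 95.2 (86.8 to 104) in cluster 2. The perforin gene Prf1 had 9 UMIs in cluster 9, a level of 5.73 (2.62 to 10.9) CPM. After thinning every barcode to 1000 UMIs, Tcf7 in cluster 9 was at 2.07 CPM, and in cluster 2 Gzmb was at 3.80 and Ifng at 0.949. In GRCm38 (mm10) annotation these genes are Gzmb (ENSMUSG00000015437) on chromosome 14 from 56258838 to 56262260, Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892, Pdcd1 (ENSMUSG00000026285) on chromosome 1 from 94038305 to 94052553, Lag3 (ENSMUSG00000030124) on chromosome 6 from 124904361 to 124911705, Havcr2 (ENSMUSG00000020399) on chromosome 11 from 46454935 to 46481255, Tcf7 (ENSMUSG00000000782) on chromosome 11 from 52252371 to 52283014 and Prf1 (ENSMUSG00000037202) on chromosome 10 from 61297833 to 61304680.

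Cluster 8 was led by Gzmm, Xcl1, Klra6 and Cd160. Its 10 leading genes held no marker of T or CD8 T cells, 1 NK marker, Klra7, and 1 marker of regulatory T cells, Ikzf2. Beyond those 10 genes, 5 T cell markers and both Cd8a and Cd8b1 were raised at least 2-fold over the mean of the other clusters. Cluster 8 had Ccl5, a chemokine that attracts T cells, at 7306 (7179 to 7434) CPM and Gzmb at 54.0 (43.6 to 66.1). Tcf7 was at 79.8 (67.1 to 94.3) CPM, and Ifng at 69.5 (57.7 to 83.0), or 42.7 in the barcodes over 2000 UMIs. Pdcd1 was at 6.32 (3.15 to 11.3) CPM, from 5 UMIs in set 1 and 6 in set 2, or 3.88 in those barcodes. Havcr2 had no UMI in cluster 8, with an interval that reaches 2.12 CPM. NK-like cells had cytotoxic effectors at 46873 (46245 to 47507) CPM, with Gzma at 10512 (10216 to 10814), Ccl5 at 18690.1 (18295 to 19092) and Gzmb at 1517 (1406 to 1634). With cluster 8 named among NK-like cells, the effector level of that class was 18558 CPM.

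The CD4 T-like barcodes formed 2 clusters. Cluster 3 (12.3% of barcodes, 95% interval 11.8 to 12.8%) had naive and memory T cell genes at 3315 (3253 to 3379) CPM and cytotoxic effectors at 226 (210.1 to 243). Cluster 7 (3.66% of barcodes, 95% interval 3.38 to 3.95%) carried T cell activation and costimulation genes at 4187 (4096 to 4279) CPM, against 1193 (1156 to 1231) in cluster 3. In cluster 7 the costimulatory receptor gene Tnfrsf4 was at 1126 (1079 to 1175) CPM, 1851 in set 1 and 874 in set 2, and the inhibitory receptor gene Ctla4 at 123 (108 to 139). Foxp3, the transcription factor of regulatory T cells, was at 40.7 (32.2 to 50.8) CPM in cluster 7, 78.9 in set 1 and 27.5 in set 2. In cluster 3 Foxp3 was at 1.85 (0.679 to 4.03) CPM, from 4 UMIs in set 1 and 2 in set 2. The pooled Ifng level of cluster 7, 718 (680.2 to 757) CPM, came nearly all from 1 library, with 48.6 in set 1 and 950.4 in set 2. Gzmb was at 157 (140.0 to 176) CPM there, 289 in set 1 and 111 in set 2. Proliferation genes summed to 7932 (7807 to 8059) CPM in cluster 7, 5148 (5037 to 5262) in cluster 9 and 1172 (1141 to 1202) in cluster 2. With each barcode weighted equally, the proliferation level was 4498 CPM in cluster 7 and 3162 in cluster 9.

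**Figure D2:**
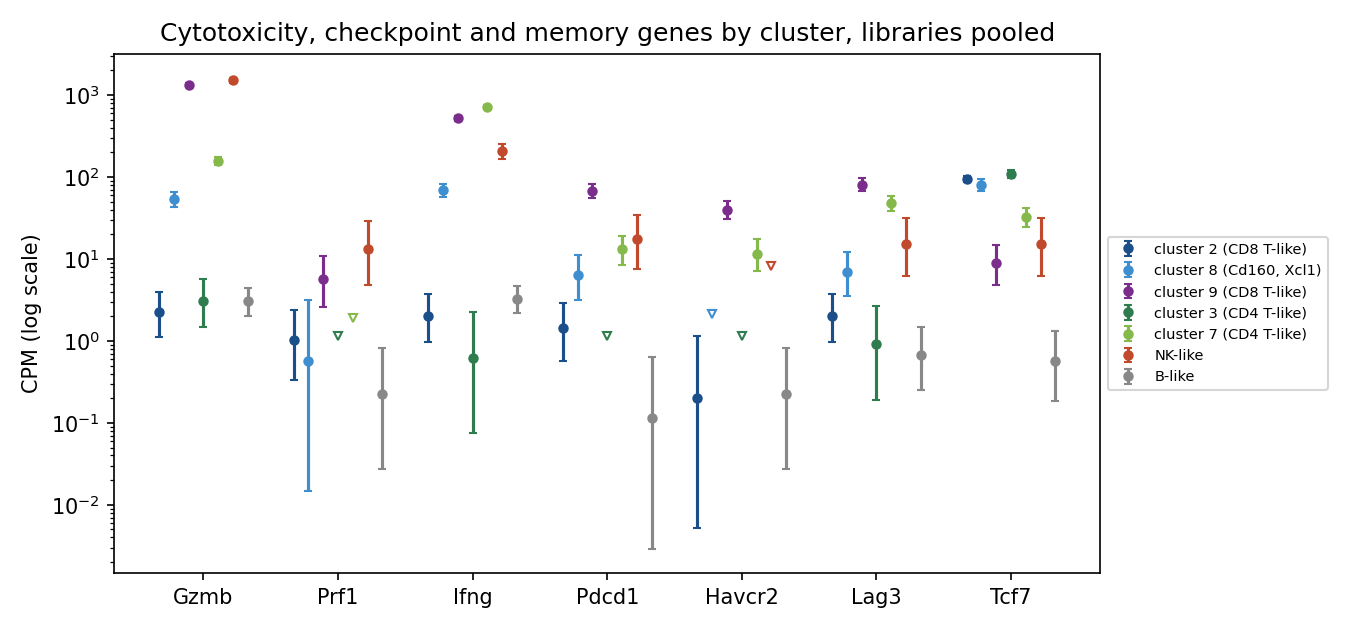
CPM (log scale) of the 7 genes fixed for CD8 T cells in T-like clusters, cluster 8, NK-like and B-like cells, both libraries pooled. Points are summed counts scaled by the total, bars exact 95% Poisson intervals, and open triangles the upper end of the interval where no UMI was counted. Gzmb lies at 1517 in NK-like cells and 1343 in cluster 9, and Tcf7 is highest in cluster 3 at 109.

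Among myeloid cells, type I interferon response genes stood at 27888 (27695 to 28082) CPM in the monocyte-like cluster and 19269 (19161 to 19378) in macrophage-like cluster 4 (7.50% of barcodes, 95% interval 7.10 to 7.91%). In the monocyte-like cluster the interferon-induced gene Isg15 was at 5719.6 (5632 to 5808) CPM and the chemokine gene Cxcl10 at 2085 (2032 to 2138). Cluster 4 had genes of alternatively activated and tumour-associated macrophages at 16820.2 (16719 to 16922) CPM, against 6938 (6842 to 7035) in the monocyte-like cluster. The mannose receptor gene Mrc1 was at 185 (174 to 196) CPM there and Arg1, which encodes an arginine-degrading enzyme, at 117 (108 to 125). The inflammatory macrophage list was at 12914 (12826 to 13004) CPM in cluster 4, with Ccl7, Ccl4 and Il1b its most abundant members, and the chemokine list at 20681 (20569 to 20794). Lipid handling and lysosome genes reached 21671 (21556 to 21786) CPM in cluster 4, 13129.8 (12867 to 13397) in cluster 15 and 10194 (10078 to 10312) in the monocyte-like cluster.

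Macrophage-like cluster 15 (0.719% of barcodes, 95% interval 0.597 to 0.859%) held 6 barcodes of set 1 and 114 of set 2, while cluster 4 held 906 and 345, so a difference between these clusters is also one between libraries. Cxcl9, a chemokine induced by interferon gamma, was at 1466 (1379 to 1557) CPM in cluster 15 and 223 (211 to 235) in cluster 4, where it was at 154 in set 1 and 381 in set 2. In cluster 15 the Cxcl9 level of set 1, 789 CPM, rests on 21 UMIs, and that of set 2 was 1492. Retnla, a gene of alternatively activated macrophages, was at 1344 (1316 to 1373) CPM in cluster 4, 877 in set 1 and 2421 in set 2. In cluster 15 it had 0 UMIs in set 1 and 3 in set 2, a pooled 4.15 (0.856 to 12.1) CPM, with 8.33 after thinning. Interferon gamma response genes summed to 6718 (6530.1 to 6909) CPM in cluster 15 and 4385 (4334 to 4437) in cluster 4. MHC class II presentation genes were at 62153 (61579.6 to 62730.4) CPM in cluster 15, with 33332 in set 1 and 63255 in set 2. They were at 27943 (27812 to 28074) CPM in cluster 4 and 72880.2 (72461 to 73301) in conventional dendritic-like cells. The conventional dendritic-like cluster was led by Cd209a and also had the mast cell protease genes Tpsb2, at 70.4 (57.9 to 84.7) CPM, and Cma1, at 84.2 (70.5 to 99.7), among its leading genes. Both came from set 1, at 122 and 146 CPM, with no UMI of either in set 2. Migratory dendritic-like cells had the chemokine gene Ccl22 at 418 (365 to 477) CPM, 472 in set 1 and 220.3 in set 2, and MHC class I presentation genes at 26352 (25916 to 26793), against 20889.9 (20777 to 21003) in cluster 4. Cd274, the gene of the checkpoint ligand PD-L1, was at 94.6 (70.2 to 125) CPM in migratory dendritic-like cells and 121 (112 to 129.7) in cluster 4.

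B-like cells carried MHC class II presentation genes at 50079 (49932 to 50227) CPM and proliferation genes at 981 (961 to 1002). Cluster 10 had proliferation genes at 12510.3 (12377 to 12645) CPM and was led by Bfsp2, Pclaf and Hmces. Its 10 leading genes held no marker of the B cell or cycling lists and 1 erythroid marker, the haemoglobin gene Hbb-bt, at 97.6 (86.2 to 110.2) CPM. Top2a, a topoisomerase of dividing cells, was at 263 (244 to 283) CPM in cluster 10 and 8.93 (7.07 to 11.1) in B-like cells, where it was at 4.94 in set 1 and 10.1 in set 2. Plasma-like cells had Jchain, the joining chain of secreted antibodies, at 25347 (24836 to 25865) CPM, 12754 in set 1 and 31418 in set 2.

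Cluster 5 (6.13% of barcodes, 95% interval 5.77 to 6.51%; 10.4% in set 1 and 3.26% in set 2) held 54.1% of the UMIs, with a median of 43859 UMIs per barcode, and no fixed marker list named it in the pooled clustering. With each set clustered alone, the RNA-rich cluster of set 1 (701 barcodes) was unnamed too, while that of set 2 (349 barcodes with a median of 44886 UMIs) was named fibroblast-like, with Sparc, Col3a1, Col1a2 and Col1a1 among its 10 leading genes. That cluster joined 324 barcodes of cluster 5 with 15 of the 16 fibroblast-like barcodes of set 2. Col1a2 had 3 UMIs in the former and 349 in the latter, and Sparc 4887 and 431. In CPM, Col1a2 was at 0.197 in the former and 3328 in the latter, and Sparc at 321 and 4110. Col3a1 was at 91.0 and 5073 CPM and Col1a1 at 7.68 and 3032. The name fibroblast-like therefore does not by itself identify cluster 5. Ptprc was at 2.29 (1.87 to 2.76) CPM in cluster 5, against 263 (251 to 276) in macrophage-like cluster 4 and 215 (203 to 229) in T-like cluster 2. Among its leading genes were the homeobox gene Rhox5, at 942 (933 to 951) CPM, the transcription factor gene Fosl1, at 173 (169.6 to 177), and the actin-binding protein gene Cald1, at 399 (393 to 405). Glycolysis and hypoxia genes summed to 14342 (14308 to 14376) CPM in cluster 5 and 7276 (7209.7 to 7343) in cluster 4. Genes of TGF-beta and immunosuppressive mediators summed to 5990.0 (5968 to 6012) CPM in cluster 5, 4579 (4474 to 4686) in cluster 9 and 4036 (3987 to 4086) in cluster 4.

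Genes of one class were also counted in others. Rhox5 was at 26.7 (23.4 to 30.3) CPM in B-like cells, 40.5 in set 1 and 22.6 in set 2, and at 18.7 (15.1 to 22.9) in cluster 2. Cd79a was at 18.3 (14.7 to 22.5) CPM in cluster 2, 6.93 in set 1 and 23.7 in set 2. In cluster 4 Cd79a was at 69.5 (63.2 to 76.4) CPM, 15.9 in set 1 and 193 in set 2, against 4088 (4046 to 4130.3) in B-like cells. Dissociation and stress genes summed to 6816 (6752 to 6881) CPM in cluster 4, 2391 (2348 to 2434) in cluster 2 and 2424 (2392 to 2457) in B-like cells. Leaving mitochondrial, ribosomal protein and haemoglobin genes out of the totals raised the levels by 1.31 to 2.74 times, depending on the cluster.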

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

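The tests on cluster 5 and on the share of B-like barcodes were chosen after the results were seen, as were the looks at the embedding table and at the barcodes left out and the tests on Cd74 without the barcodes rich in it. The bounds of both other tests on Cd74 were written before their values.

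The embedding table, which the report does not use, has 7863 entries, and 7863 barcodes of the count table have over 2000 UMIs. That minimum came from a search over many minimums of UMIs and genes, some with mitochondrial limits or a need for Ptprc, so the equal number alone carries little weight. With the barcodes in file order, detection of a gene was correlated with its mean in the 10 nearest entries. The median correlation over 7 genes was 0.805, from 0.278 for Foxp3 to 0.829 for Cd3d. With the order shifted by 1 entry the highest was 0.0920, and with as many barcodes chosen by their number of genes 0.100.

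The cell filter left out 3314 barcodes, 3266 of set 1 and 48 of set 2. They carried Rhox5, a leading gene of cluster 5, at 437 CPM (397 to 481). This is above 3.06 CPM, the level of 3 UMIs, which was set as the limit for a count of 0. That limit does not single Rhox5 out, since Cd74, at 1862 CPM, Cd79a, at 178, the macrophage gene C1qa, at 173, and Cd3d, at 102, passed it too, so the values do not show what these barcodes are. Of the barcodes left out, 3085 had fewer than 200 genes, with a median of 110 UMIs, and all 3085 were of set 1.

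The first pattern weighed is cluster 5, RNA-rich barcodes in a sort for CD45. If each droplet also held an immune cell of median UMIs, Ptprc, Coro1a and Laptm5 together would reach 57.3 CPM, but they reached 17.1 (16 to 18.3), 0.299 of that level, which argues against an immune cell in each droplet but not in some. Ptprc alone, in CPM, was at 1.64% of its lowest level among immune clusters of 500 or more barcodes, that of B-like cluster 0. This argues against immune cells with much RNA in which Ptprc rises with the total. Cluster 0 had a median of 1216 UMIs and cluster 5 43859, so part of the gap comes from the larger totals. Immune cells in which Ptprc did not rise with the total are not covered. Non-immune cells that passed the sort for CD45, which should remove them, stay open: fibroblast markers summed to 524 (517 to 530.3) CPM, led by Sparc and Col3a1, and tumour or epithelial markers to 402 (396 to 408), led by Wfdc2 and Krt8, with Krt8 at 100.1 (97.2 to 103) and Epcam at 0.577 (0.380 to 0.840). The fibroblast sum does not hold for all its members. In the cluster 5 barcodes of set 2, Col1a2 was at 0.197 CPM and Col1a1 at 7.68. The fibroblast-like barcodes that joined them when set 2 was clustered alone had 3328 and 3032. The sum by itself therefore does not identify fibroblasts. An effect of the treatment was not tested, because barcodes could not be tied to treatments.

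The second pattern is the higher share of B-like barcodes, those of cluster 10 included, in barcode set 2, at 47.5% (95% interval 46.5 to 48.5%) against 24.5% (95% interval 23.4 to 25.5%) in set 1. The lowest UMI count of a kept barcode was 256 in set 1 and 840 in set 2. With 840 UMIs as the minimum in both, the shares were 47.5% (46.5 to 48.5%) and 23.1% (22.1 to 24.2%), a ratio of 2.05, which argues against the minimum as the whole cause. Dissociation and sorting, the mice pooled and the treatment stay open, and no biological explanation was tested.

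The third pattern is the higher level of MHC class II genes in T-like clusters, NK-like cells and cluster 8 of barcode set 2. It was not confined to them. The median log2 ratio of set 2 over set 1 was 0.97 in monocyte-like cells, 0.90 in macrophage-like cells and 0.74 in cluster 5. It was 0.19 in B-like cells, 0.18 in cluster 10 and 0.15 in conventional dendritic-like cells. The tests here cover only the T-like clusters, NK-like cells and cluster 8. Of the 3711 such barcodes in set 2, the 84 with 10 or more UMIs of Cd74, the invariant chain of MHC class II, held 58.2% of the Cd74 UMIs and 82.1% of them had a Cd79a or Cd79b UMI, consistent with B cells in the same droplets, while set 1 had 17 such barcodes among 2336, which held 53.3% of the Cd74 UMIs, 47.1% of them with a Cd79a or Cd79b UMI. Leaving them out took Cd74 from 653 to 286 CPM in set 2 and from 252 to 120.2 in set 1. Its ratio of set 2 over set 1 went from 2.59 (2.43 to 2.75) to 2.38 (2.17 to 2.61) over these clusters together. In cluster 2 the ratio went from 4.11 (3.34 to 5.11) to 3.87 (3.14 to 4.81). In cluster 3 it went from 3.34 (2.87 to 3.91) to 4.43 (3.71 to 5.30). In cluster 8 it went from 5.69 (3.87 to 8.69) to 2.40 (1.62 to 3.71). In cluster 9 it went from 1.58 (1.33 to 1.89) to 2.29 (1.70 to 3.13). The limit set for the lower bound was 1.5. Clusters 2 and 3 lay far above it, which argues against such droplets as the whole difference there. In clusters 8 and 9 the lower bounds lay near that limit. These intervals treat UMIs as independent, while Cd74 varied between barcodes of cluster 2 beyond counting error. For clusters 8 and 9 the test therefore cannot decide. In NK-like cells the ratio went from 15.7 (9.59 to 27.6) to 1.94 (1.12 to 3.55) and in cluster 7 from 1.28 (1.18 to 1.40) to 0.749 (0.632 to 0.891), so such droplets stay open as the whole difference in both. Of the 84 barcodes of set 2, 44 were in cluster 7, 17 in NK-like cells and 11 in cluster 8. Only 7 were in cluster 9, 4 in cluster 2 and 1 in cluster 3. In cluster 2 of set 2, thinned to 1000 UMIs, the variance of Cd74 over its mean was 1.63. This is above the 1 of counting error alone and under the bound of 2 set for free RNA spread over all droplets. The mean was 0.278 Cd74 UMIs per barcode, at which low expression by the cells themselves could also stay under that bound. The value therefore leaves free RNA open but does not single it out. Without the barcodes rich in Cd74, the B cell gene Cd79a was also higher in these clusters of set 2, at 23.1 CPM against 9.08 in set 1. B cell RNA in the droplets thus differed between the sets as well. Expression by the T and NK cells themselves stays open, since no biological explanation was tested.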

How the results depend on the processing

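Of 76 alternative values of 6 pooled shares, 31 stayed within the counting interval of the main value and 45 did not. The main values, as the naming rule gave them with cluster 8 among CD8 T-like and cluster 10 among B-like barcodes, were 38.2% B-like, 19.2% CD8 T-like, 16% CD4 T-like, 1.10% NK-like, 13.7% monocyte- and macrophage-like, and 2.91% dendritic. Without a filter on barcodes, shares were 33.7% B-like, 12.8% CD8 T-like, 18.2% CD4 T-like, 11.5% monocyte- and macrophage-like and 2.30% dendritic. With the stricter filter, shares were 19.1% B-like, 10.3% CD4 T-like, 1.81% NK-like, 19.7% monocyte- and macrophage-like and 4.16% dendritic. At resolution 0.5, shares were 15.8% CD8 T-like and 4.46% NK-like. At resolution 2, shares were 15.6% CD8 T-like and 12.2% monocyte- and macrophage-like. With marker genes per cell, shares were 30.2% B-like, 17.8% CD8 T-like, 1.51% CD4 T-like, 0.623% NK-like and 5.17% monocyte- and macrophage-like. With each barcode set clustered alone, shares were 8.55% CD8 T-like and 3.46% NK-like. Without neutrophil-like and non-immune barcodes in the denominator, shares were 41.0% B-like, 20.6% CD8 T-like, 17.2% CD4 T-like and 14.7% monocyte- and macrophage-like. Over 2000 UMIs, shares were 14.9% B-like, 28.9% CD8 T-like, 3.90% CD4 T-like, 1.62% NK-like, 22% monocyte- and macrophage-like and 4.83% dendritic. Without Scrublet scores over 0.25, shares were 16.1% CD8 T-like, 4.29% NK-like and 13% monocyte- and macrophage-like. Clustered without the list genes, shares were 16.4% CD8 T-like, 17.3% CD4 T-like, 2.57% NK-like and 12.2% monocyte- and macrophage-like. Under the first naming rule, shares were 35.5% B-like, 15.7% CD8 T-like, 4.51% NK-like and 12.9% monocyte- and macrophage-like. Without the rules on mixed clusters, shares were 40.0% B-like. With clusters 8 and 10 unnamed, as in the report, shares were 35.5% B-like and 15.7% CD8 T-like. Barcodes over 2000 UMIs, the Scrublet score, the clustering without list genes, both earlier naming rules and the lack of a name for clusters 8 and 10 were chosen after seeing the data, as was leaving out clusters 5 and 18. The stricter filters remove small barcodes by construction, and the naming rules only rename clusters 8, 10, 11 and 15; for the other settings the cause was not tested. Without a filter the cluster that scored highest for NK markers, with 609 barcodes, was named CD8 T-like and counted there, so that setting gives no NK-like share, and marker genes per cell define no dendritic class. Of 297 alternative list levels, 22 were over 1.5 times higher and 14 over 1.5 times lower than the main level. Of 690 alternative levels of 115 genes and lists in clusters, 115 used other totals, which by construction raised all of them, 75 by over 1.5 times. Of the other 575, 5 were over 1.5 times higher and 14 over 1.5 times lower. Of 348 alternative medians of barcode set 2 over set 1 in 3 lists, 337 kept their sign, 114 of 116 for type I interferon response genes, and 11 changed it, 2 of them past the counting interval: cytotoxic effectors in cluster 1 went from 0.38 to -0.43 on the log2 scale with members of at least 50 UMIs, and MHC class II genes in cluster 10 from 0.18 to -0.052 after thinning to 1000 UMIs, for which the cause was not tested. Thinning left out 762 barcodes of set 1 and 486 of set 2. Of 230 places filled by the ratio rule, 140 were held by genes with at least 200 UMIs. Removing Scrublet's own calls was not run, since it made none, and for pooled levels neither a median-of-ratios scaling, which needs a second sample, nor a pseudocount applies. No paired analysis was possible because each treatment has 1 library and barcodes are not tied to treatments. Levels that rest on few UMIs are the least certain: Prf1 had 9 UMIs in cluster 9, and whether depth was the cause was not tested.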

Other observations

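The values here belong to barcode set 1 and barcode set 2, each 1 library whose treatment is not known here, so no direction between treatments follows from them and they have no replicate check. Which to give was chosen after the data had been seen. Type I interferon response genes had a median log2 ratio of set 2 over set 1 of -1.19 in CD4 T-like cluster 7, -0.99 in conventional dendritic-like cells, -0.61 in B-like cells and -0.40 in cluster 2, each at percentile 0 of the matched random lists. The median was above 0 in cluster 9, at 0.07 (percentile 86.9), and in the RNA-rich cluster 5, at 0.06 (percentile 99.5). Monocyte- and macrophage-like barcodes, which also carried interferon response genes, made up 23.5% of set 1 and 6.98% of set 2. Of the leading genes of macrophage-like cluster 4, Ccl8 had log2 ratios of -1.19 in B-like cells and -0.68 in cluster 2, but Retnla 0.57 and 0.45. Whether free RNA of myeloid cells adds to the interferon ratios in other cells was not tested. In the B-like class Isg15, a ubiquitin-like protein induced by interferon, was at 252 CPM (230.5 to 275) in set 1 and 72.2 (65.9 to 78.8) in set 2, and Ifi27l2a, another interferon-induced gene, at 3481 CPM (3400.2 to 3563) in set 1 and 1318 (1291 to 1346) in set 2. Cluster 0 gave 1203 and cluster 1 366 of these barcodes in set 1, and 2532 and 1829 in set 2. The Isg15 level in CPM was 247 in set 1 and 70.6 in set 2 within cluster 0, and 264 in set 1 and 73.8 in set 2 within cluster 1.

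The sets also differed in the effector genes of their T-like clusters. In CD8 T-like cluster 9 the granzyme gene Gzmc was at 777 CPM (707 to 851) in set 1 and 33.8 (23.3 to 47.5) in set 2, Gzmd at 584 CPM (524 to 648) in set 1 and 104 (84.3 to 126) in set 2 and Gzmf at 1439 CPM (1344 to 1539) in set 1 and 276 (244 to 311) in set 2. Gzma was at 159 CPM (129 to 195) in set 1 and 910.4 (851 to 972) in set 2, Gzmk at 88.9 CPM (66.6 to 116) in set 1 and 276 (244 to 311) in set 2 and Gzmb at 1147 CPM (1063 to 1237) in set 1 and 1463 (1388 to 1541) in set 2. At resolution 2 these barcodes split into a cluster led by Gzmk, with 64 of set 1 and 279 of set 2, and a cycling cluster led by Gzmf, with 81 and 67, so the mix of both differed between the sets. Within the cluster led by Gzmf the levels in CPM were 990.5 in set 1 and 59.9 in set 2 for Gzmc, 746 and 288 for Gzmd, 1833 and 747 for Gzmf, 77.2 and 522 for Gzma, 60.0 and 234 for Gzmk and 1153 and 1759 for Gzmb. Within the cluster led by Gzmk they were 455 and 1129 for Gzma, 193 and 299 for Gzmk and 1125 and 1297 for Gzmb, and Gzmd had no UMI. Gzmc there was at 7.71 and 19.2 CPM, from 1 and 12 UMIs, and Gzmf at 23.1 and 11.2, from 3 and 7 UMIs. In CD4 T-like cluster 7, Ifng was at 48.6 CPM (31.1 to 72.3) in set 1 and 950.4 (900.4 to 1003) in set 2, and Penk, which encodes an enkephalin precursor, at 488 CPM (428 to 553) in set 1 and 49.3 (38.4 to 62.3) in set 2. Foxp3 was at 78.9 and 27.5 CPM in the same cluster. The mix of regulatory and other T cells in it may therefore also differ between the sets, which was not tested. Macrophage-like barcodes had Saa3, an acute-phase gene, at 48.0 CPM (41.7 to 54.9) in set 1 and 1559 (1511 to 1608) in set 2. This came from cluster 15, led by Lyz1 and Saa3 and nearly all of set 2: the Saa3 level in CPM within cluster 4 was 48.2 in set 1 and 21.5 in set 2.

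For the other fixed lists, the median log2 ratio of set 2 over set 1 over all cells, with and without clusters 5 and 18, and over 12 classes or clusters ranged from 0.15 to 3.09 for MHC class II presentation and from -0.66 to 1.49 for cytotoxic effectors. It was -1.23 to 0.19 for chemokines, -0.38 to 0.13 for glycolysis and hypoxia, -0.76 to 0.13 for lipid handling and lysosome, -0.19 to 0.45 for T cell activation and costimulation, -0.37 to 0.50 for inhibitory receptors and exhaustion, -0.13 to 0.67 for naive and memory T cells, -0.42 to 0.57 for proliferation, -0.47 to 0.56 for interferon gamma response, -0.12 to 0.40 for MHC class I presentation, -0.80 to 0.06 for alternatively activated and tumour-associated macrophages, -0.67 to 0.11 for inflammatory macrophages, -0.69 to 0.26 for TGF-beta and immunosuppressive mediators and -0.50 to 0.15 for dissociation and stress. The highest of these ratios for MHC class II was in NK-like cells, where 17 of 130 barcodes in set 2 and 0 of 53 in set 1 had 10 or more Cd74 UMIs. Without those barcodes it was 0.91. The highest for cytotoxic effectors was in cluster 10 and rests on genes of T and NK cells, among them Nkg7, Ccl5 and Gzma, in a cluster where 8.60% of the barcodes had UMIs of both a Cd3 gene and Cd79a or Cd79b. The interferon gamma median was 0.37 in B-like cells, 0.35 in cluster 2 and 0.56 in cluster 3. In monocyte-like cells it was 0.39, in macrophage-like cells 0.26 and in cluster 5 0.24. These values each stood at percentile 100. Below 0 were NK-like cells, at -0.47, cluster 7, at -0.18, cluster 8, at -0.09, and all cells without clusters 5 and 18, at -0.05.

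CD8 T-like clusters 2 and 9 made up 13.7% (95% interval 12.9 to 14.6%) of set 1 and 17.1% (95% interval 16.4 to 17.9%) of set 2, and CD4 T-like barcodes 18.4% (95% interval 17.5 to 19.4%) and 14.3% (95% interval 13.6 to 15%). NK-like barcodes made up 0.787% (95% interval 0.590 to 1.03%) of set 1 and 1.31% (95% interval 1.09 to 1.55%) of set 2. With at least 840 UMIs in both sets, clusters 2 and 9 made up 14.3% of set 1 and 17.1% of set 2, CD4 T-like barcodes 18.6% and 14.3% and NK-like barcodes 0.783% and 1.31%. Among barcodes over 2000 UMIs, with the same classes, clusters 2 and 9 made up 13.3% of set 1 and 25.8% of set 2, and monocyte- and macrophage-like barcodes 39.8% and 14.5%. CD4 T-like barcodes made up 6.20% and 9.30%, the opposite order to that over all kept barcodes.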
